A study of Homo sapiens with 6 samples.

How the data were processed

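Total RNA of TFK-1 cells was labelled with Cy3 and hybridised to Agilent one-colour expression arrays, 1 array per sample, per the labels' protocols. The deposited values of each array are linear spot intensities from Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. The processed intensity is background-subtracted and detrended, with surrogate values for spots not above background, per the file headers. Mean and local background intensities of each spot are given beside it, per the file headers. The authors also gave processed values of the same arrays, taken here as log2 values, since their differences between groups match those of quantile-normalized log2 intensities. Each column of these holds the same set of values with a median of 3.08, as quantile normalization gives, and ranks as the processed intensities do. Their scale and the tool behind them are not given in the sources used here, and no centring per probe was seen. All columns of per-array values were used for their own sample.

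Each array had 62976 spots, of which 4259 were controls. The 58717 other spots held 50599 probes, 49697 of them as 1 spot. The files name probes by accession. Of the probes, 30878 had a RefSeq accession, and 28174 of these matched a gene symbol (20503 different symbols) in a RefSeq table of assembly GRCh38.p14, while 22425 probes kept the name in the files. No genome build is named with the array, so no coordinates are given. XIST and genes of the Y chromosome are not named.

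The main values were log2 of the processed intensity minus the 75th percentile of the array over its probes other than controls. Control spots and spots marked as non-uniform or population outliers (288 to 367 per array) were left out, no spot was saturated, and spots of 1 probe were averaged. A probe counted as well above background where at least 0.5 of its spots were. Probes well above background on all 3 arrays of at least 1 group were kept, with the probe of highest mean signal for each gene, which left 19113 genes, 13815 of them with a symbol. Of 3674 genes with several probes, 55 that changed had another probe that changed the opposite way. The 75th percentile of the signal was 92.8, 143 and 102 for replicates 1, 2 and 3 labelled TSA, and 106, 77.1 and 107 for those labelled as without TSA.

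The groups were taken from the labels, and the 3 arrays of each were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, adjusted p below 0.05). Signed values are arrays labelled TSA minus arrays labelled as without TSA. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 41 lists with at least 5 measured genes, and again with an estimated correlation and with fry. Of the 1099 genes listed, 877 were measured. For a gene not well above background on any array of 1 group, the fold is a bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value of any probe well above background on that array.

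The groups, tests, gene lists, first alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 largest rises and 12 largest falls among changed genes with a symbol, well above background on all 6 arrays and without overlap between the groups. It also named the 5 rises and 5 falls with the largest bounds among genes detected in 1 group alone. It took the 4 changed members with the largest change of each list that passed and at most 2 of every other list. CDKN1A, TYMS, MYC, CCND1, EZH2, HDAC1 to HDAC11, CDH1, VIM, BCL2L1 and BCL2L11 were named whatever their values. Some genes and 1 gene list that these rules name are not reported here.

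The steps were tested on simulated arrays with the means and spread of the 19113 genes of this comparison. Of 67 genes changed by 0.5 in log2, 2.99% were recovered, of 67 changed by 1, 40.3%, and of 66 changed by 2, 89.4%, with 8 false calls (8.33% of the calls). Far fewer genes changed in the simulation than the 9721 that passed in the data. This makes the adjusted threshold stricter in the simulation, so these shares do not give the recovery in the data. A simulated shift of the epithelial list by 1 was found among the 41 lists, along with 1 other list. The simulated genes varied independently of each other. The simulation therefore does not show how the list test behaves where genes of a list are correlated. Alternatives covered other scalings (quantile, array median, spike-in probes, the authors' table), normexp background correction with an offset of 50, other filters and probe choices, replicate number and slide as blocks, an intensity trend, array weights and leaving out each array in turn. A percentile over probes detected on all arrays and quantile normalization within slide 1 were added after the data were seen.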

Results

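Gene expression was measured in TFK-1, a human cell line established from a cholangiocarcinoma, a cancer of the bile duct epithelium. Of 6 one-colour arrays, 3 carried RNA labelled as from cells exposed to TSA for 48 h and 3 carried RNA labelled as from cells without TSA. TSA is the usual abbreviation of trichostatin A, an inhibitor of histone deacetylases (HDACs), the enzymes that remove acetyl groups from histones and other proteins. The labels give the abbreviation alone and set the dose at the IC50 of the cells, without a concentration. The series names core targets of the compound in cholangiocarcinoma as its question. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

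Each array read 50599 probes besides its controls. In arrays labelled TSA, 45.6%, 48.8% and 43.8% of the probes were well above background in replicates 1, 2 and 3. In arrays labelled as without TSA the shares were 48.3%, 48.2% and 54.3%. The number of arrays limits the precision of every value. Over the 19113 genes tested, log2 values correlated at 0.992 to 0.993 between arrays labelled TSA, at 0.966 to 0.993 between arrays labelled as without TSA, and at 0.919 to 0.943 between the groups, where genes are not independent replicates. Slide 1 held all 3 arrays labelled TSA and control replicates 1 and 2, whereas slide 2 held only control replicate 3, which also had the highest share of probes above background. Values within slide 1, which are the same as those with slide as a block, are therefore given beside the counts and the gene lists.

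**Figure D1:**
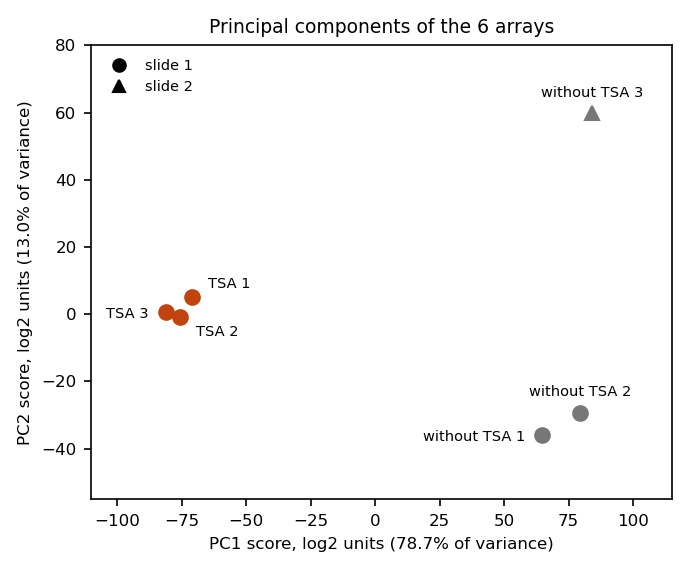
Scores of the 6 arrays on the first principal components of the log2 values of 19113 genes, in log2 units, with colours for the labelled group and symbols for the slide. The groups lay apart on the component with 78.7% of the variance, and control replicate 3, the array of slide 2, lay apart on the component with 12.98%.

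Genes of cell division were higher, and many genes of neurons and the metallothioneins were lower, in arrays labelled TSA than in arrays labelled as without TSA. The lists of mitosis, replication, neuronal and metallothionein genes did not pass camera with an estimated correlation between genes (adjusted p = 0.342 for each). PCLAF, a partner of the replication clamp PCNA, was 13.7-fold higher (log2 fold change 3.78, SE 0.18, 3 arrays per group, limma adjusted p = 2.36e-05). CCNA2, the cyclin of S phase and mitosis, was 11.8-fold higher, and TYMS, which makes thymidylate for DNA, was 10.97-fold higher. VGF, a precursor of neuropeptides, was 67.5-fold lower (log2 fold change -6.08, SE 0.28), and STMN2, a neuronal regulator of microtubules, was at least 26.6-fold lower. These directions run against those known for HDAC inhibitors, as 18 of the 19 changed members of the readout lists described further on did, so each group is named by its label throughout.

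With limma, 9721 of the 19113 genes tested changed, 5829 of them higher and 3892 lower in arrays labelled TSA. A change of at least 2-fold was found for 5032 genes, 2581 higher and 2451 lower. When only genes well above background on all 6 arrays were tested, 2378 were at least 2-fold higher and 1205 lower. The median log2 fold change of all genes was 0.11, and for 11743 genes (61.4%) the values of the groups did not overlap, where chance gives 10%. Within slide 1, 10714 genes changed, 6302 higher and 4412 lower, and 9330 of the 9721 were among them with the same direction. That comparison reuses arrays and scaling of the main values, so it does not test the scaling. With quantile normalization 8143 genes changed, 4133 higher and 4010 lower, and 6898 of the 9721 stayed changed in the same direction. With spike-in probes as the scale 3902 of the 9721 did. How the changed genes divided between higher and lower depended on the scaling. The share that was higher was 60.0% with the 75th percentile of each array, 82.5% of 11158 genes with the median of each array, and 39.8% of 4049 genes with spike-in probes. With a percentile taken only over probes detected on all 6 arrays, an alternative added after the data were seen, 35.7% of 9533 genes were higher. These scalings moved every gene by the same amount, 0.56, -0.09 and -0.36, and the median of all genes to 0.67, 0.02 and -0.25. With spike-in probes all 4049 genes changed at least 2-fold, so smaller changes no longer passed. The share with spike-in probes is therefore not the effect of the shift alone.

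Among genes well above background on all 6 arrays, CPNE7, a copine that binds phospholipids, had the largest rise by label (log2 fold change 3.90, SE 0.24, limma adjusted p = 4.29e-05). Among the next were PCLAF, the histone gene H2BC7 (3.74) and IFITM1 of the interferon-induced transmembrane proteins (3.73). The log2 fold changes of H3C15, CCNA2, H2AC11, TYMS, the splicing factor SRSF2, FXYD3, a regulator of the sodium pump, and CDCA7 lay between 3.56 for H3C15 and 3.34 for CDCA7. MIR7-3HG, the host transcript of a microRNA 7 precursor, had the largest fall by label (-7.14, SE 0.29, adjusted p = 2.06e-05). It was followed by RFPL4A (-6.18), VGF, CEND1 of neurons (-5.75), TEX19 of germ cells (-5.42), RGMB-AS1 (-5.07), and GAST, which encodes the hormone gastrin (-4.99). The log2 fold changes of KRTAP2-3, DAPL1, the neural adhesion molecule NCAM1, FTCD of folate metabolism and GOLGA6L6 lay between -4.76 for KRTAP2-3 and -4.08 for GOLGA6L6. The histone genes, RFPL4A, KRTAP2-3 and GOLGA6L6 have near-identical relatives that can share a probe, so their values are uncertain as to the gene.

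Genes detected in 1 group alone were more often those detected without TSA by label. Of the genes tested, 778 were well above background on all 3 arrays labelled as without TSA and on none labelled TSA, and 770 of these changed. The reverse held for 88 genes, of which 83 changed. Over all genes and with 2 arrays of each group, the ratio of the counts lay between 2.21 (896 against 405) and 5.02 (1246 against 248) in the 3 pairings without control replicate 3, and between 4.55 and 12.3 in the 6 with it. Besides STMN2, SPANXA1 of the testis, one of several near-identical copies, was at least 29.3-fold lower in arrays labelled TSA, ARL14 at least 15.5-fold, NTS, the precursor of neurotensin, at least 13.7-fold, and IRGM at least 13.6-fold. In the other direction VPS35L was at least 5.58-fold higher, FBN3 at least 5.04-fold, APOBEC3G, a cytidine deaminase that restricts retroviruses, at least 4.30-fold, MX1 at least 4.11-fold and SNORA75 at least 3.68-fold. Adjusted p for these 10 genes lay between 1.81e-05 for STMN2 and 0.00013 for VPS35L.

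Of 43 gene lists, 41 had enough measured genes for the list test, and 22 passed it, 17 upward and 5 downward in arrays labelled TSA. Within slide 1, 17 lists passed, all of them among the 22. In camera with the correlation between genes estimated from the data, no list passed over all arrays or within slide 1, with 2 lists at an unadjusted p below 0.05 over all arrays, and 35 lists passed in fry, which tests for a shift in 1 direction without comparing a list with other genes. The median of each of the 22 lists kept its direction in all 9 scalings, except the list of genes commonly raised by HDAC inhibitors and the drug transport list, which turned with the median of each array, where every gene moved up by 0.56. Both lists lay below the median of all genes in all 9 scalings, the main one included. A scaling that moves every gene alike cannot change this position, and the authors' table nearly repeats quantile normalization. The 9 scalings are therefore not independent checks. Counts adjusted over the list alone were the same as those over all genes unless given.

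All 42 measured genes of mitosis and the spindle were higher in arrays labelled TSA, with a median log2 fold change of 2.23 (2.19 within slide 1). CCNB2, a cyclin of mitosis, was higher by 3.19 (SE 0.15), the kinase gene AURKB by 3.08 and the transcription factor gene FOXM1 by 2.87. Of 39 genes of DNA replication, 38 were higher and 1 did not pass, with a median of 1.87 (1.88 within slide 1). Examples were CDC45 (3.03), GINS2 (2.67) and RRM2 of ribonucleotide reductase (2.65), along with TYMS. Purine and pyrimidine synthesis had 24 of 26 genes higher and none lower (25 adjusted over the list alone), with a median of 1.40 (1.29 within slide 1), among them PAICS (2.36) and DUT (2.07). The list of G1 cyclins and kinases, which also held E2F factors and other regulators, had 13 of 15 genes higher and none lower. Its median was 1.49 (1.51 within slide 1), and its largest changes were those of SKP2 (2.50), E2F1 (2.42), CDC25A (2.33) and E2F2 (2.19). Of 27 genes of homologous recombination and Fanconi anaemia repair, 19 were higher and 1 lower (20 and 1 adjusted over the list alone), with a median of 1.65 (1.59 within slide 1), as for RAD54L (2.90), FANCA (2.66) and BRCA1 (2.39). These 5 lists passed camera with adjusted p between 3.72e-17 for mitosis and 8.44e-05 for the G1 genes, and adjusted p = 0.342 with an estimated correlation for each.

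Replication-dependent histone genes, which supply nucleosomes in S phase, were higher for 33 and lower for 6 of 52 genes (34 and 6 adjusted over the list alone), with a median of 1.28 (1.32 within slide 1) and camera adjusted p = 4.95e-06. Adjusted p = 0.579 with an estimated correlation. H3C7 and H3C2, both at 3.30, stood beside H2BC7 and H2AC11, and all of them have near-identical copies. Of 11 replacement histone variants 7 were higher and 2 lower (camera adjusted p = 0.0792, not passed), with CENPA of centromeres at 2.71 and H2AX at 2.42. Among 8 inhibitors of cyclin-dependent kinases, 4 were higher and 3 lower (adjusted p = 0.803, not passed). CDKN2A was higher by 2.14, and CDKN2B was lower at -1.72 and well above background on 2 of the 3 arrays labelled TSA. CDKN1A, which encodes p21, had a log2 fold change of -0.51 (SE 0.18, adjusted p = 0.0468). Its call was lost without any 1 of 5 arrays, namely TSA replicate 1 (adjusted p = 0.093) or 2 (0.157) and control replicate 1 (0.0821), 2 (0.124) or 3 (0.0516). It did not pass in 10 of 21 alternatives, with adjusted p from 0.00476 to 0.901 over all of them.

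Genes commonly lowered by HDAC inhibitors in cultured cells were higher in arrays labelled TSA for 12 of 14 and lower for none, with a median of 2.00 (1.95 within slide 1) and camera adjusted p = 8.44e-05. Adjusted p = 0.342 with an estimated correlation. They included CCNB1 (2.64, SE 0.20), along with TYMS, BRCA1 and the apoptosis inhibitor gene BIRC5 (2.39), which also stand in other lists. Genes commonly raised by such inhibitors were lower for 6 and higher for 1 of 13, with a median of -0.35 (-0.50 within slide 1) and camera adjusted p = 0.0297. With an estimated correlation adjusted p = 0.342 here too. The list did not pass in 3 of 21 alternatives, which were those without control replicate 2 (adjusted p = 0.0522), with the median of each array (0.0934) and with spike-in probes (median -0.44, adjusted p = 0.175). CLU, which encodes the chaperone clusterin, was lower at -2.47 (SE 0.15), the metallothionein gene MT1X at -2.11 and H2BC12 at -0.93 (lost in 3 of 21 alternatives, adjusted p up to 0.308), and the tubulin gene TUBB3 was the exception at 1.34. With the median of each array as the scale, which moved every gene up by 0.56, the raised list had a median of 0.20 and CDKN1A a log2 fold change of 0.05. Relative to the median of all genes both were the same as in the main values, at -0.46 and -0.62. An equal shift of all genes cannot change this. The list lay between -0.76 and -0.33 in all 9 scalings, some of which are such shifts.

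**Figure D2:**
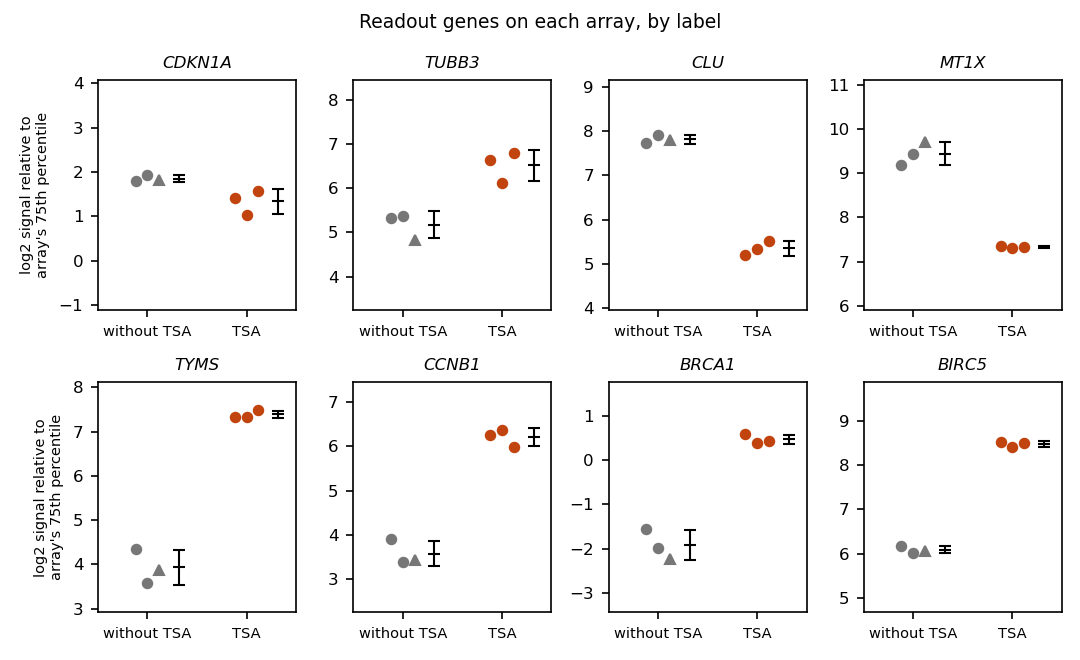
Log2 signal of 8 readout genes relative to the 75th percentile of each array, with 1 point per array (circles for slide 1, triangles for slide 2) and the mean with SD of each labelled group beside the points. Each panel spans the same range of log2 units. CDKN1A, CLU and MT1X lay lower, and TUBB3, TYMS, CCNB1, BRCA1 and BIRC5 higher, on all 3 arrays labelled TSA. With the median of each array as the scale, which moved every gene up by 0.56, CDKN1A turned direction, while it stayed at -0.62 relative to the median of all genes.

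Of 17 histone deacetylases and sirtuins, 5 were higher and 1 lower (camera adjusted p = 0.391, not passed). HDAC5 was higher by 1.94 (SE 0.18, adjusted p = 0.00018), HDAC7 by 0.92, HDAC1 by 0.90, HDAC6 by 0.46 and SIRT3 of mitochondria by 1.01. The calls of HDAC1 (adjusted p = 0.258) and HDAC6 (0.456) were lost with quantile normalization. That of HDAC6 was also lost without TSA replicate 2 (0.102) or 3 (0.104) and without control replicate 1 (0.0557) or 2 (0.0889). In all, HDAC6 did not pass in 12 of 21 alternatives (adjusted p up to 0.745) and HDAC1 in 5 (up to 0.449). HDAC7 did not pass with spike-in probes (0.196) or with the percentile over detected probes (0.56, adjusted p = 0.0806), and SIRT3 with spike-in probes (0.143). HDAC2 (0.39, adjusted p = 0.16), HDAC3 (0.44, adjusted p = 0.0998), HDAC4 (-0.09, adjusted p = 0.722), HDAC8 (-0.40, adjusted p = 0.105), HDAC10 (-0.59, adjusted p = 0.238) and HDAC11 (0.42, adjusted p = 0.11) did not pass, HDAC10 being well above background on 2 of the 3 arrays labelled TSA, and HDAC9 was not among the genes tested. HDAC11 passed upward in 7 of 21 alternatives, among them that within slide 1 (0.58, adjusted p = 0.0189). HDAC8 passed downward in 3, among them that without TSA replicate 1 (-0.58, adjusted p = 0.0368), and HDAC10 with array weights (-0.91, adjusted p = 0.0296). With the median of each array, which moved every gene up by 0.56, HDAC2 (0.95, adjusted p = 0.0172) and HDAC3 (1.00, adjusted p = 0.0114) passed upward and HDAC4 (0.47) and HDAC8 (0.15) turned without passing. HDAC3 also passed upward with normexp and the 75th percentile (0.53, adjusted p = 0.0327). HDAC2 and HDAC3 were below 0 in 4 settings with quantiles, down to -0.30 and -0.35, and HDAC3 passed downward in that within slide 1 (adjusted p = 0.0413). HDAC4 was above 0 without TSA replicate 1 (0.04) or control replicate 1 (0.02). Among 14 histone acetyltransferases and bromodomain readers 7 were higher and 1 lower (adjusted p = 0.0834, not passed), with HAT1 at 1.13 (0.0884 with spike-in probes) and KAT2A at 0.96, which did not pass in 3 of 21 alternatives (adjusted p up to 0.169). Polycomb and DNA methyltransferase genes were higher for 11 and lower for 3 of 21, with a median of 0.76 and camera adjusted p = 0.049. The list did not pass within slide 1 (median 0.49, adjusted p = 0.144) or in 10 of 21 alternatives in all (adjusted p from 0.000646 to 0.217), and adjusted p = 0.667 with an estimated correlation. UHRF1, which guides maintenance of DNA methylation, was higher by 2.85, DNMT3B by 2.23, DNMT1 by 1.60, RBBP7 by 1.55 and EZH2, the Polycomb methyltransferase, by 0.93 (SE 0.15, adjusted p = 0.189 with spike-in probes).

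Neuronal genes were lower in arrays labelled TSA for 16 and higher for 4 of 30 (16 and 5 adjusted over the list alone), with a median of -0.64 (-0.55 within slide 1) and camera adjusted p = 0.00156. Adjusted p = 0.342 with an estimated correlation. On genes well above background on all 6 arrays the list did not pass (median -0.24, adjusted p = 0.0799), and over 21 alternatives its median ran from -0.99 to -0.08. After STMN2 and VGF, SYT11 of synaptic vesicles was at least 5.29-fold lower and STMN4 at least 4.42-fold lower. Metallothioneins, small proteins that bind zinc and copper, were lower for 9 of 10 and higher for none, with a median of -1.65 (-1.62 within slide 1) and camera adjusted p = 1.13e-05. Adjusted p = 0.342 with an estimated correlation here too. MT1F was lower at -2.09 (SE 0.14), MT1M at -1.84 and MT1E at -1.76, and these genes are close copies of each other. Of 11 measured germline and cancer/testis genes, 3 were lower and 1 higher (adjusted p = 0.137, not passed). TEX11 was lower at -1.98 and was well above background on 1 of the 3 arrays labelled TSA.

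The list of ribosome biogenesis genes and MYC targets had 27 of 31 genes higher and none lower (29 adjusted over the list alone). Its median was 0.83 (0.76 within slide 1), with UTP4 at 1.45, NOLC1 at 1.37, DKC1 at 1.21 and SRM at 1.16. With spike-in probes DKC1 (adjusted p = 0.0616) and SRM (0.076) did not pass, and SRM did not with normexp and quantiles (0.0703). Heat shock protein genes were higher for 12 of 16 and lower for none (13 adjusted over the list alone), with a median of 1.38 (1.41 within slide 1). HSPA8 was higher by 2.61 (SE 0.18), HSPD1 of mitochondria by 2.17, HSPA1B by 2.14 and HSPH1 by 2.05. HSPA1A of the same list, a close relative of HSPA1B, did not pass in limma (0.17, adjusted p = 0.602). Cholesterol synthesis and uptake had 17 genes higher and 1 lower of 24, with a median of 1.07 (0.94 within slide 1), as for ACAT2 (1.52) and MVD (1.48). The mitochondrial respiratory chain had 22 of 33 genes higher and none lower (23 adjusted over the list alone), with a median of 0.68 (0.67 within slide 1), as for COX5A (1.38), ATP5MC1 (1.30), COX8A (1.23) and NDUFB8 (1.14). Its call was lost with quantile normalization (median 0.12, adjusted p = 0.381) and in 4 of 21 alternatives in all (adjusted p up to 0.627). COX8A (0.0541) and NDUFB8 (0.0829) did not pass with spike-in probes. Camera adjusted p for these 4 lists lay between 4.95e-06 for ribosome biogenesis and 0.000316 for heat shock and cholesterol. Adjusted p = 0.376 with an estimated correlation for cholesterol and 0.342 for the other 3 lists.

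The integrated stress and unfolded protein responses had 15 genes higher and 2 lower of 26, with a median of 0.71 and camera adjusted p = 0.0272. The list did not pass within slide 1 (median 0.69, adjusted p = 0.0755) or in 10 of 21 alternatives in all (adjusted p from 0.00215 to 0.416), and adjusted p = 0.376 with an estimated correlation. HSPA5, the chaperone of the endoplasmic reticulum, was higher by 2.02 and PSAT1 of serine synthesis by 1.45, and the transcription factor genes ATF3 (-1.94) and DDIT3 (-1.52), which stress induces, were lower. Fatty acid and triglyceride synthesis had 10 genes higher and 2 lower of 20 (adjusted p = 0.216, not passed), with the desaturase genes FADS2 at 2.30 and SCD at 2.17. In glycolysis and hypoxia, 11 genes were higher and 3 lower of 28 (adjusted p = 0.207, not passed), with PGAM1 at 1.82 and LDHA at 1.39. Lysosome and autophagy had 13 genes higher and 7 lower of 36 (adjusted p = 0.615, not passed), with CTSZ at 2.12 and UVRAG at least 2.09-fold higher, which was lost with normexp and the 75th percentile (adjusted p = 0.453).

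Epithelial adhesion and keratin genes were higher for 19 of 28 and lower for none (19 and 1 adjusted over the list alone), with a median of 0.65 (0.64 within slide 1) and camera adjusted p = 0.000654. Adjusted p = 0.342 with an estimated correlation. PKP3 of desmosomes was higher by 1.81 (SE 0.18), the tight junction genes CLDN7 by 1.67 and CLDN4 by 1.65, EPCAM by 1.51 and CDH1, which encodes E-cadherin, by 1.45. Actin and tubulin cytoskeleton genes were higher for 21 and lower for 2 of 31 (22 and 2 adjusted over the list alone), with a median of 0.99 (0.87 within slide 1) and camera adjusted p = 0.000241. Adjusted p = 0.342 with an estimated correlation. TPM2 was higher by 2.51, STMN1 by 2.22 and TUBA1B by 2.08, whereas CNN1 of smooth muscle was lower at -4.07 and was well above background on 1 of the 3 arrays labelled TSA. Mesenchymal genes were higher for 9 and lower for 7 of 22 (adjusted p = 0.914, not passed), with a median of 0.11, a mean of -0.02 and a downward test, and the median was above 0 in 5 of 9 scalings. TGFBI was lower at -4.20, with 1 of the 3 arrays labelled TSA well above background, VIM, which encodes vimentin, was lower at -1.54 (SE 0.20), and S100A4 was higher by 2.80.

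**Figure D3:**
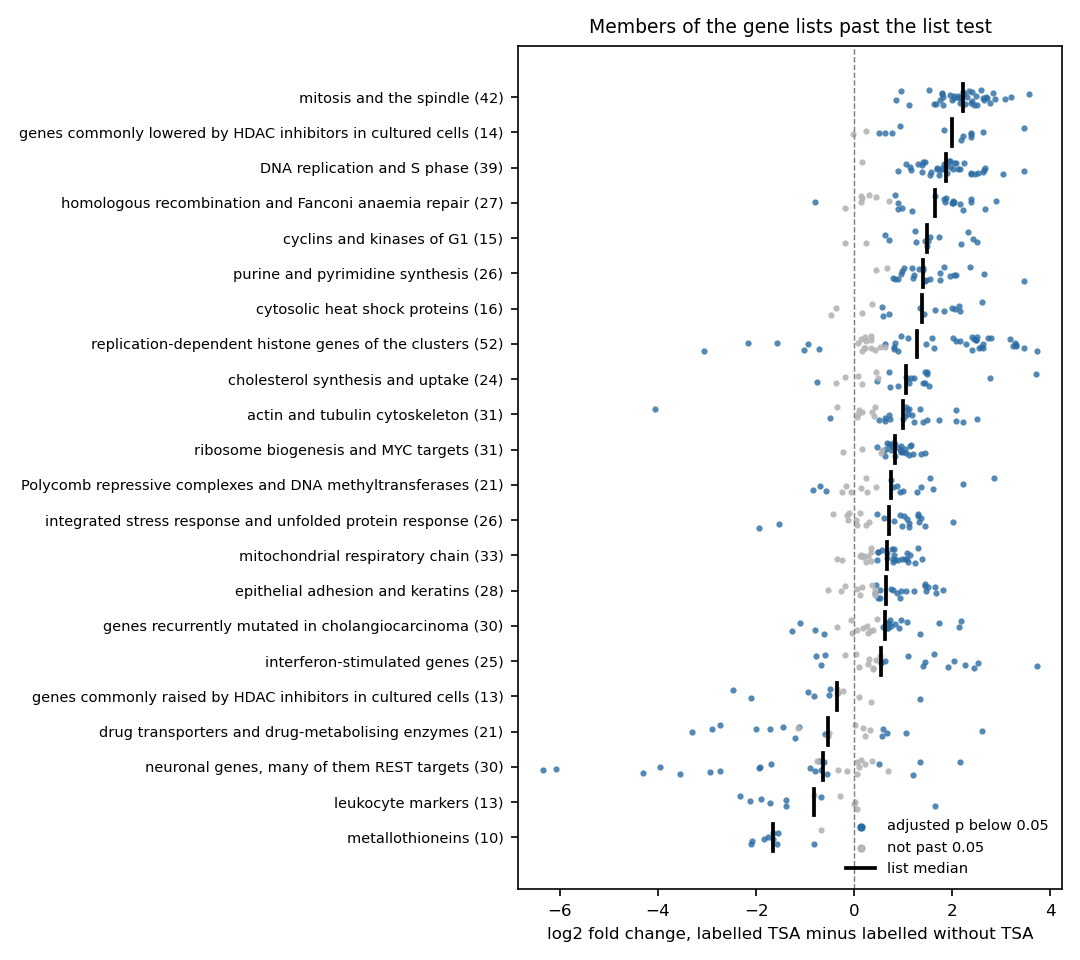
Log2 fold change (arrays labelled TSA minus arrays labelled as without TSA) of each measured member of the 22 lists that passed the list test, with 1 point per gene and the list median as a bar. Numbers in brackets count measured members. The lists labelled as cytosolic heat shock proteins and as cyclins and kinases of G1 also hold other genes, as given in the text. Medians ran from 2.23 for mitosis to -1.65 for the metallothioneins. Those of the genes commonly raised by HDAC inhibitors and of drug transport turned direction with the median of each array as the scale. That scale moved every gene up by 0.56. Both medians lay below the median of all genes in all 9 scalings, which scalings that move every gene alike cannot change.

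Biliary epithelium markers had 7 genes higher and 4 lower of 17 (7 and 5 adjusted over the list alone, adjusted p = 0.803, not passed), with ANXA4 at 2.21 and FXYD2 at least 4.90-fold lower. Of 7 measured hepatocyte markers 3 were lower and 1 higher (adjusted p = 0.0792, not passed), with APOA1 at -1.34 and AHSG at -1.13 (adjusted p = 0.075 with the median of each array). Drug transporters and drug-metabolising enzymes were lower for 9 and higher for 5 of 21 (10 and 5 adjusted over the list alone), with a median of -0.54 and camera adjusted p = 0.049. This list did not pass within slide 1 (median -0.37, adjusted p = 0.112) or without control replicate 1 (adjusted p = 0.0651), nor in 11 of 21 alternatives in all (adjusted p from 0.0132 to 0.288). Adjusted p = 0.342 with an estimated correlation. Its median was 0.02 with the median of each array as the scale, which moved every gene up by 0.56. There the list still passed downward (adjusted p = 0.0179), at -0.65 relative to the median of all genes, as in the main values. The aldo-keto reductase genes AKR1C3 (-3.31, SE 0.20) and AKR1B10 (-2.91) were lower, the efflux pump gene ABCB1 was at least 3.97-fold lower, and the transporter gene ABCC3 was higher by 2.61.

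Interferon-stimulated genes were higher for 13 and lower for 3 of 25, with a median of 0.55 (0.52 within slide 1) and camera adjusted p = 0.00764. Adjusted p = 0.432 with an estimated correlation. On genes well above background on all 6 arrays the list did not pass (median 0.44, adjusted p = 0.103), and over 21 alternatives its median ran from 0.20 to 1.11. IFITM2 (2.52) and IFITM3 (2.45), close relatives of IFITM1, were higher, as was MX1. MHC presentation and NK-cell ligands had 7 genes higher and 4 lower of 25 (adjusted p = 0.848, not passed), with TAPBP at 3.28 and TAP2 at 2.31, which both serve peptide loading of class I molecules. NF-kappaB targets and inflammatory cytokines had 6 genes higher and 8 lower of 15 (adjusted p = 0.383, not passed), with the chemokine gene CCL2 at least 3.08-fold lower and TNFAIP2 at 2.58. Leukocyte markers, fixed as signs of other cells, were lower for 7 and higher for 1 of 13, with a median of -0.82 and camera adjusted p = 0.0264. The list did not pass within slide 1 (median -0.66, adjusted p = 0.118) or in 8 of 21 alternatives in all (adjusted p from 0.00861 to 0.288), and adjusted p = 0.342 with an estimated correlation. CD3E was at least 3.11-fold lower (adjusted p = 0.0303), ITGAX at least 2.40-fold, CD2 at least 1.79-fold (adjusted p = 0.0173), and CSF1R was lower at -1.91. CD3E had log2 values of -2.52, -2.73 and -0.30 in control replicates 1, 2 and 3. Its bound therefore leans on control replicate 3, the array of slide 2. The calls of CD3E (adjusted p = 0.0718) and CD2 (adjusted p = 0.0626) were lost with quantile normalization, and that of CD3E also without TSA replicate 2 (0.0674) or 3 (0.102). Over 20 alternatives CD3E did not pass in 8 (adjusted p up to 0.199), CD2 in 6 (up to 0.183) and ITGAX in 1 (0.0703). Too few fibroblast and endothelial markers were measured for a list test, 3 of each. COL1A1 (2.08) and FBLN1 (1.96) were higher, and VWF was lower at -2.13, with another probe of VWF changed the opposite way.

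Apoptosis-promoting genes were higher for 9 and lower for 2 of 26 (adjusted p = 0.111, not passed), with BID at 2.74 and BMF, both BH3-only proteins, at -2.97. BCL2L11, another of that class, did not pass (0.34, adjusted p = 0.234). It was below 0 in 3 of 21 alternatives, down to -0.31, and passed upward with the median of each array (0.90, adjusted p = 0.0231). Apoptosis-inhibiting genes had 6 higher and 4 lower of 16 (6 and 5 adjusted over the list alone, adjusted p = 0.882, not passed), with BIRC5, the decoy receptor gene TNFRSF10C at -2.11 and BCL2L1 at 0.64 (adjusted p = 0.00955, lost in 5 of 21 alternatives with adjusted p up to 0.431). Immediate early genes had 6 higher and 5 lower of 23 (5 and 5 adjusted over the list alone, adjusted p = 0.692, not passed), with CCN2 at -2.57 and ATF3. Their median was 0.10, their mean -0.15 and the test ran downward, with the median above 0 in 4 of 9 scalings.

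Targets of the WNT, Notch and Hedgehog pathways had 6 genes higher and 5 lower of 22 (adjusted p = 0.803, not passed), with the Notch target HEY1 at least 9.60-fold lower and ASCL2 at least 2.05-fold lower. Growth factor receptors and RAS feedback genes had 9 higher and 3 lower of 25 (8 and 3 adjusted over the list alone, adjusted p = 0.373, not passed), with ERBB2 at 2.17 (SE 0.17) and ERBB4 at least 2.83-fold lower. MYC had a log2 fold change of 0.64 (SE 0.20, adjusted p = 0.0335) that was 0.00 with quantile normalization (adjusted p = 0.992), and its call was lost without TSA replicate 2 (adjusted p = 0.114) or 3 (0.0923), and in 10 of 21 alternatives in all. CCND1, which encodes cyclin D1, did not pass (0.24, adjusted p = 0.377). It was below 0 in 5 of 21 alternatives, down to -0.38, and passed upward with the median of each array (0.79, adjusted p = 0.0393). Genes recurrently mutated in cholangiocarcinoma were higher for 16 and lower for 4 of 30, with a median of 0.63 and camera adjusted p = 0.0445. The list did not pass within slide 1 (median 0.45, adjusted p = 0.198) or in 10 of 21 alternatives in all (adjusted p from 0.000674 to 0.314), and adjusted p = 0.667 with an estimated correlation. It held ERBB2, CDKN2A and KMT2D (1.35).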

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

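Settings that take the percentile over detected probes or normalize by quantiles within slide 1 were chosen after the data were seen, and the others before. Over all alternatives, 3254 comparisons of single named genes with their reported value kept direction and side of the threshold, 73 lost the call, 24 gained one and 23 turned direction, and of those of the lists that passed, 403 kept both, 57 lost the call and 2 turned. Slide as a block gives the values without control replicate 3, and both count among the 21 alternatives. The authors' table nearly repeats quantile normalization, and both count as well. Most named genes were picked by the size of their change in the main values, so these counts do not give the stability of all calls. Of the 9721 changed genes, 6898 stayed changed in the same direction with quantile normalization and 3902 with spike-in probes. With the median of each array as the scale, 9200 genes were higher and 1958 lower, and 8053 changed at least 2-fold (6573 and 1480). There the medians of the genes commonly raised by HDAC inhibitors (0.20) and of drug transport (0.019) turned, as did HDAC8 (0.15), HDAC4 (0.47) and CDKN1A (0.045), because this scale moved every gene up by 0.56, and relative to the median of all genes none of them moved. With spike-in probes as the scale 4049 genes changed, 1611 higher and 2438 lower, each of them at least 2-fold. Normexp, whose offset shrinks the folds of dim genes by construction, left 2395 genes at least 2-fold changed (626 lower) with the 75th percentile and 1670 (802 and 868) with quantiles. Testing only genes well above background on all 6 arrays left 2378 at least 2-fold higher and 1205 lower, since it removes genes not well above background on every array. With the percentile over detected probes 3399 genes were higher and 6134 lower, and 1284 at least 2-fold higher, while CCND1 (-0.12) and BCL2L11 (-0.018) turned, as every gene moved down by 0.36. Quantile normalization turned HDAC2 (-0.10), CCND1 (-0.25) and HDAC3 (-0.15), as did normexp with quantiles (-0.10, -0.21 and -0.11) and the authors' table (-0.10, -0.24 and -0.15). Quantiles within slide 1 turned HDAC2 (-0.30), CCND1 (-0.38), HDAC3 (-0.35), MYC (-0.17) and BCL2L11 (-0.11), which was also turned by the mean of its probes (-0.31). Of the gene values that turned, only HDAC3 with quantiles within slide 1 passed the test (adjusted p = 0.0413), and the drug transport list still passed with the median of each array (adjusted p = 0.0179, downward). The cause of the turns with quantiles and with the mean of probes was not tested. Camera with an estimated correlation passed 0 lists and fry passed 35. Leaving out each array in turn gave 7615 to 10714 changed genes (4474 to 6302 higher, 3141 to 4412 lower), 4766 to 5454 at least 2-fold (2469 to 2879 higher, 2297 to 2575 lower) and 17 to 22 lists, with HDAC4 between -0.18 and 0.037. With replicate number as a block (replicate block), 8532 genes changed, 5013 of them at least 2-fold, and 20 lists passed. The numbers did not pair the arrays, as deviations of arrays with the same number correlated at -0.17, -0.04 and -0.04 and 0 of 6 arrays correlated best with their own number. Signal over background limits the dim genes. Folds are bounds for genes not well above background on any array of 1 group. Genes well above background on only some arrays of a group carry measured values, which dim signal limits too.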

Other observations

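The tests of symbol families and of chromosomes, those of exchanged labels, of an exchanged array and of scaling, that on spike-in probes, and the present form of those on detection were chosen after the results were seen, as was the bound that would have counted against an excess of long non-coding RNA or X chromosome genes. Long non-coding RNA genes made up many of the genes lower in arrays labelled TSA, with 192 of 542 at least 2-fold lower against 1256 of 13808 genes with a symbol (Fisher's exact test, which takes genes as independent, odds ratio 6.29, adjusted p = 9.92e-67). Besides MIR7-3HG and RGMB-AS1, and chosen after their values were seen, LINC00624 had a log2 fold change of -3.96, BTG2-DT -3.49 and KDM7A-DT was at least 11.03-fold lower. Over 10 bins of mean signal the odds ratio was 3.54 (95% interval 2.90 to 4.31), against 6.29 without bins. Low signal may thus account for part of the excess. The bins argue against mean signal as its whole source. They do not test the detection filter, which kept 778 genes detected only without TSA by label, against 88 only with it. Genes kept that way are lower by label through the filter itself. Many of the long non-coding RNA genes were not well above background on every array labelled TSA, and those detected on all 6 arrays were not tested apart. The part due to the filter therefore stays open. The odds ratio without bins was above 1 with p below 0.05 in all 9 scalings, with 73 to 250 of the genes at least 2-fold lower. Genes of small RNAs that guide modification of other RNAs went the other way, with 42 of 94 SNORA genes (odds ratio 4.11, adjusted p = 2.29e-08) and 10 of 21 SCARNA genes (4.58, adjusted p = 0.0242) at least 2-fold higher. Over 9 scalings the counts ran from 19 to 75 and from 4 to 16, the adjusted tests passed in 8 and 5, and the odds ratios were above 1 in all 9. SNORA23 had a log2 fold change of 2.58, SNORA2C 2.44 and SCARNA20 1.98. Whether these probes read the small RNAs or longer transcripts that contain them was not tested. SNORD genes showed no such excess, with 16 of 111 higher and 13 lower (adjusted p = 0.947 and 0.778).

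Of 22 HLA genes, 10 were at least 2-fold lower in arrays labelled TSA and none higher (odds ratio 8.38, adjusted p = 0.000453). All 10 are of MHC class II, whose main molecules present peptides to helper T cells, and they include the pseudogene HLA-DPB2. HLA-DQB1 had a log2 fold change of -2.00, HLA-DRA -1.41 and HLA-DPB1 -1.20. The DRB genes among them are near-identical copies that can share a signal. Fisher's exact test takes them as independent, so it may overstate the excess. With the median of each array as the scale 2 of 22 were at least 2-fold lower (Fisher's exact test, odds ratio 1.83, p = 0.317, not passed), although all 10 were still below 0. Aldo-keto reductase genes were lower for 6 of 13 (odds ratio 8.60, adjusted p = 0.018), with AKR1B15 at -3.19 and AKR1C1 at -2.00, and genes with CYP symbols for 9 of 27 (5.02, adjusted p = 0.0167), with CYP4F12 at -2.17 and CYP1A1 at -1.71. GOLGA genes, many of them near-identical copies, were lower for 11 of 21 (odds ratio 11.1). Among genes at least 2-fold higher were 7 of 11 SRSF splicing factors (odds ratio 8.81, adjusted p = 0.018), with SRSF7 at 2.47 and SRSF6 at 1.81. They also held 14 of 23 genes with nucleoporin symbols (7.86, adjusted p = 0.000166), with NUP210 at 2.86 and NUP85 at 1.94, and 12 of 27 kinesins (4.03, adjusted p = 0.018), with KIF20A at 2.84 and KIF2C at 2.65. Of 312 tests of symbol families 14 passed, 11 for an excess and 3 for a deficit, and those of MCM, ANKRD, ZNF and RPL genes are not described. With the same adjustment within each of 9 scalings, the excess passed in 9 for nucleoporin symbols, 8 for HLA and GOLGA genes, 7 for kinesins, 6 for aldo-keto reductases, 5 for CYP symbols and 4 for SRSF genes. The odds ratios were above 1 in all 9, down to 1.53 for kinesins. The counts ran from 2 to 10 for HLA genes, 3 to 6 for aldo-keto reductases, 3 to 10 for CYP symbols, 3 to 13 for GOLGA genes, 4 to 10 for SRSF genes, 7 to 22 for nucleoporin symbols and 7 to 14 for kinesins.

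Readouts of HDAC inhibition ran against the labels, with 18 of the 19 changed members of the readout lists moving against the direction known for such inhibitors. A signal-dependent bias as the whole source was argued against by quantile normalization within slide 1. The medians of the lowered and raised lists lay 2.33 apart there and 2.36 apart in the reported values. A scaling that moves every gene alike cannot change this difference, so such a scaling was not tested. The count of 18 of 19 holds for the reported values, and the raised list had a median of 0.20 with the median of each array. An exchange of a single array between groups was argued against too, since the lowest correlation within a group (0.966) lay 0.0232 above the highest between groups (0.943). An exchange of the labels of the whole groups remains a candidate explanation. So does a response of TFK-1 cells to 48 h of TSA that differs from that of other cells, which was not tested.

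Control replicate 3, the single array of slide 2, stood apart from the other control arrays. Spike-in probes, which hold no RNA of the cells, deviated with an SD of 0.631 on this array and of 0.135 to 0.226 on the others, so a difference in slide, scan or hybridisation may account for part of the distance. A shift that depends on signal alone was argued against, since after quantile normalization the array correlated with the other controls at no more than 0.969, against 0.992 for the least correlated arrays labelled TSA. A separate culture or RNA sample behind this array stays open and was not tested.

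More genes were detected only in arrays labelled as without TSA (778 against 88). The higher detection rate of control replicate 3 may account for part of the excess. With 2 arrays of each group and over all genes, the ratio was 4.55 to 12.3 in the 6 pairings with this array and 2.21 to 5.02 in the 3 without it. The lowest, 896 against 405 genes (95% interval 1.97 to 2.49, which takes genes as independent), spans the bound of 2, so the part due to this array cannot be told. A lower sensitivity of the arrays labelled TSA stays open too. A common floor on quantile-normalized values of slide 1 gave 724 and 448 genes, a ratio of 1.62 (693 and 349 over the genes tested, 1.99), but quantile normalization puts about as many probes above a floor on each array, which draws this ratio towards 1, so the test decides nothing. The rest stays open, with a difference in expression between the labelled groups among the explanations, untested.

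X chromosome genes were at least 2-fold lower for 55 of 461, with an odds ratio of 1.37 (95% interval 1.01 to 1.83) that did not pass over 46 tests of chromosomes (adjusted p = 0.189). Of these tests 2 passed, both on genes at least 2-fold higher, with an excess on chromosome 17 (179 of 875, odds ratio 1.32, adjusted p = 0.0444) and a deficit on chromosome 7 (79 of 650, odds ratio 0.684, adjusted p = 0.0444). They passed in 3 and 2 of 9 scalings, and X in 0. Over the 10 splits of the 6 arrays into 3 and 3, the labelled split gave 9721 changed genes and 5032 at least 2-fold, and the highest of the others 0 for both, so 1 of 10 splits gave as many. For the lists it gave 22 and the highest other gave 22, with 3 of the 10 splits reaching that number. The smallest share these splits can give is 0.1, which is too few for a share under 0.05.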
